A study of Homo sapiens with 6 samples.

How the data were processed

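Two-colour arrays of 14080 probes measured RNA of the GM00156 cell line on 6 occasions. Per the labels, mRNA of emetine-treated cells was labelled with Cy3 and mRNA of untreated cells with Cy5, spot intensities were averaged after background subtraction, and each sample's intensity was divided by that of its reference. Which channel is the reference is not stated for these cells. Per the labels' protocols, the authors normalised ratios within each slide by a ratio statistics method that uses housekeeping genes, and discarded ratios whose quality value was below 0.5. The deposited table holds a log2 ratio for each probe and array. The log base was settled from the values, since 2 to the power of the value was a multiple of 1 in 10000, within 0.05 of a multiple, for 99.5% to 100% of the values of each array. No centring between arrays was found, as the column medians differ from 0. The direction of the ratio remains unknown. Because zero is set on each slide by housekeeping genes, a shared shift of those genes would move every ratio of that array.

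The table has 0 missing values and no quality column. Each array repeats a single value at 333 to 534 probes (0.52, 0.88, 2.06, 1.06, 0.40 and 0.99 in the order self-self, 0 min, 10 min, 30 min, 1 h and 8 h). Of 989 probes at this value on at least 1 array, 59 were there on all 6, and 91.5% of those have no gene symbol against 16.5% of all probes. These entries were treated as not measured, which was decided after seeing the data, and keeping them was run as an alternative. After that, 13080 probes were measured on all 6 arrays and 13140 on all 5 harvests.

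Gene symbols came from the platform annotation, updated through gene IDs. Of the probes, 11304 have 1 gene symbol, 446 several and 2330 none, and 11282 of the single-gene probes matched the gene table. They name 8974 genes. Probes with several symbols were named by none, 13 probes for sex-linked transcripts were left out of everything, and no genome coordinates are given because the sources used here name no build. Among 1533 genes with more than 1 probe, 98 had probes past the threshold on both sides. GAPDH was not among these 98, although its 8 probes ranged from -0.87 to 0.28 in mean log ratio. Only the lowest passed (limma adjusted p = 0.00626). On the self-self array that probe was at -0.18 and the others were between 0.40 and 0.49.

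The groups follow the labels, with 1 array each: self-self, and emetine-treated against untreated at 0, 10, 30 min, 1 h and 8 h. The design, gene lists, named-gene rule and alternatives were fixed before the data were examined, except for the alternatives named as added after seeing the data. Each harvest was compared with the central 99% of the self-self array over probes measured on all 6 arrays, without a test. Then limma 3.58.1 in R 4.3.3 fitted a mean and a slope on centred log2(1 + min / 10) to each probe over the 5 harvests, with 3 residual degrees of freedom, empirical Bayes moderation and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. All tests are two-sided. As each harvest is a different time, the spread behind every p-value is that around a line over 5 arrays.

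Gene lists were tested with camera at a preset correlation of 0.01, on genes with probes averaged, over the 25 lists with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera tests on the 3 residual degrees of freedom, so it could hardly call a list here. The lists cover immediate-early genes and regulators with AU-rich mRNA, nonsense-mediated decay targets, spliceosome, ATF4 program, cytokines with unstable mRNA, ribosomal proteins, translation factors, ribosome biogenesis, histones, p53 targets, G2/M and G1/S genes, cytosolic and endoplasmic reticulum chaperones, proteasome, oxidative phosphorylation, cholesterol, glycolysis, interferon-stimulated genes, apoptosis regulators, and markers of fibroblasts, B lymphocytes, T and NK cells and epithelium, with common reference genes. They were written from general knowledge and share some members. Random lists for the closing tests were drawn 10000 times from all tested genes and were not matched on abundance, which ratios do not give.

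Genes named for the mean were the 12 per side with the largest mean among single-gene probes measured on all 6 arrays that passed, had the same sign on all 5 harvests and exceeded their self-self value in size. Of the 12 on the positive side, 10 are described and drawn. For the slope they were 6 per side with the smallest p-values, since none passed. For each list, up to 4 members with the largest mean in size were eligible. Genes named beside a slope list, and the fifth and later members of a list, were chosen after their values were seen.

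The tests were tried on simulated values for the same 13140 probes and 5 arrays. For the mean, 22.7% of probes with a true value of 0.5 were recovered, 94.0% with 1 and 100% with 2, with 12 false calls. For the slope, 13.6% were recovered at 0.25, 100% at 0.5 and 100% at 1, with 8 false calls. The simulated noise was normal and independent between probes, at each probe's moderated SD. In the measured values SNAI2 did not pass with a slope of 0.97, so these shares do not give the power there. A low count of slopes therefore does not show that slopes of 0.5 or more are absent. A list shifted by 0.5 was called (camera adjusted p = 2.55e-38) and 0 of 21 lists that share no gene with it. Genes were simulated as independent there, while the measured lists had estimated correlations of up to 0.66. False calls of lists through correlated genes were therefore not tested. Alternatives covered centring, scaling to equal spread, the limit of the self-self range, probe filters, the self-self array as the level to compare with, a mean without a slope, other time scales, robust moderation, averaging of probes, other list tests, and leaving out each harvest in turn. Figures were drawn with matplotlib 3.10.9. Depth does not apply to arrays, and precision is limited by their number.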

Results

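A set of 6 two-colour arrays followed the human cell line GM00156, held by the Coriell repository, through a block of translation and then of transcription. Emetine, an alkaloid that stops ribosomes from moving along mRNA, was given at 100 µg/ml for 10 h. Actinomycin D, which stops RNA synthesis, was then added at 5 µg/ml to treated and untreated cells. Cells were harvested at 0, 10 and 30 min and at 1 and 8 h, and on each of 5 arrays RNA of emetine-treated cells was set against RNA of untreated cells of the same harvest. On the remaining array, RNA of treated cells harvested at 0 min was hybridised with itself (self-self). Treatments of this kind have been used to find transcripts that cells degrade only while translation runs, such as the targets of nonsense-mediated decay.

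Every harvest had 1 array and no replicate, so the number of arrays limits the precision of every value. The deposited values are log2 ratios whose numerator the labels do not state, so the sides are called positive and negative here and no direction of change is given. The 0 min array carries a conflict in its labels, since its channel names give treated and untreated RNA while its description gives treated RNA on both sides. Counts without this array are given beside some of the main ones, not all. The cell type is not stated in the labels.

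Log ratios on the self-self array were tight, with a median of 0.01 and a robust SD of 0.12. The medians of the 0, 10 and 30 min, 1 h and 8 h arrays were 0.05, 0.08, 0.15, 0.06 and 0.15, and their robust SDs were 0.44, 0.91, 0.78, 0.53 and 0.87. Across 13080 probes measured on all 6 arrays, the 5 harvests correlated with each other at a mean Pearson's r of 0.79, from 0.66 to 0.89. The self-self array correlated with them at a mean r of 0.23, from 0.18 to 0.33. These correlations run across probes, which are not independent replicates. The 0 min array correlated at 0.89 with the 10 min array and at 0.24 with the self-self array, and its robust SD was 0.44 against 0.12. These values argue against treated RNA on both sides of the 0 min array, which its description gives. On the 1 h array large positive values were missing. The 163 probes whose mean at 30 min and 8 h was above 3 all lay lower at 1 h than at both, and the highest 1 h value was 2.10 among probes measured at all 5 harvests.

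**Figure D1:**
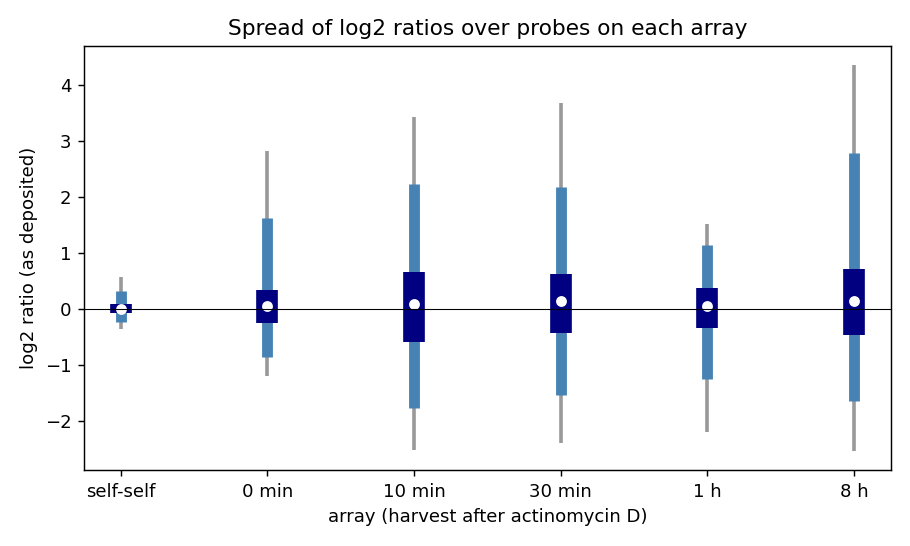
Spread of the deposited log2 ratios (vertical axis) over the measured probes of each of the 6 arrays (horizontal axis). White points are medians, thick bars span the central 50%, medium bars the central 95% and thin lines the central 99% of probes; the robust SD rises from 0.12 on the self-self array to between 0.44 and 0.91 on the harvests.

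The comparison of each harvest with the self-self array asks how many log ratios lie beyond the noise of labelling and hybridisation. It does not separate the treatment from other differences between treated and untreated cultures, since the self-self array holds 1 RNA on both sides. Of the genes chosen for their mean over the harvests, the largest positive was TNFAIP3, an inhibitor of NF-kB signalling, at 5.49, 6.58, 6.90, 1.36 and 6.38 at 0, 10 and 30 min, 1 h and 8 h. The largest negative was TUBA1A, an alpha-tubulin, at -0.94, -3.91, -3.41, -3.09 and -4.35. Their self-self values were -0.04 and -0.18. The central 99% of the self-self array ran from -0.32 to 0.46. Outside it lay 5169 probes (39.5%) at 0 min, 8823 (67.5%) at 10 min, 8278 (63.3%) at 30 min, 5992 (45.8%) at 1 h and 8296 (63.4%) at 8 h. Their positive and negative counts were 2451 and 2718, 4367 and 4456, 4374 and 3904, 2537 and 3455, and 4399 and 3897. No p-value goes with these counts, since each harvest has 1 array. At every harvest 1390 probes lay beyond the range on the positive side and 1709 on the negative side; without the 0 min array these were 1742 and 2288, and without the 1 h array 1757 and 1892. The sign was the same on all 5 arrays for 62.5% of probes, where 5 independent signs give 6.25%. Without the 0 min array it was the same on 4 arrays for 67.8%, where independent signs give 12.5%. The arrays share 1 dye orientation and may share 1 pair of cultures. Their signs need not be independent, so these shares do not measure reproducibility. The counts rest on the arrays' unequal spread. After scaling to equal spread, 8, 0, 0, 18 and 0 probes lay outside, and a limit of 1 log2 unit gave 952, 3623, 2746, 1087 and 3670.

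The mean log ratio over the 5 harvests asks which transcripts differed across the whole course. The genes with the largest positive means included the stress and immediate-early genes EGR4, GADD45B, ATF3 and FOS, and those with the largest negative means included the tubulins TUBA1A, TUBA3C and TUBA4A. With limma, 8047 of 13140 probes passed an adjusted p of 0.05, of which 4597 were positive and 3450 negative, and 8666 probes had an unadjusted p under 0.05. A mean of at least 1 in size was found for 1212 positive and 780 negative probes that passed. Without the 0 min array 7962 probes passed, 4554 positive and 3408 negative. With each array centred on its median, 7763 passed and 48.1% of them were positive, against 57.1% as deposited. When the self-self array entered the same fit as the level to compare with, 2 probes passed, and the 24 genes chosen for their mean had adjusted p-values from 0.167 to 0.187. Those 2 probes, named after their values were seen, report PCDH8 and PHKG2 and stood at 5.60 and 3.97 on the self-self array itself. In that fit a single self-self array is assumed to vary like the harvests. The harvests may come from the same pair of cultures, so all p-values here measure only the spread between harvests and arrays.

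Of the 12 genes with the largest positive means 10 are described here. TNFAIP3 led with 5.34 (SE 0.73, 5 arrays, adjusted p = 0.000703). EGR4, a zinc finger transcription factor of the immediate-early class, was at 5.22 (SE 0.71). The probe for H4C8, a histone H4 gene, was at 5.20 (SE 0.65), although near-identical H4 genes may share it. GADD45B, a growth arrest and stress gene, was at 4.53 (SE 0.68). The stress transcription factor ATF3 was at 4.35 (SE 0.54) and the orphan nuclear receptor NR4A3 at 4.22 (SE 0.52). The chemokine CXCL3 was at 4.15 (SE 0.56), the AP-1 subunit FOS at 4.11 (SE 0.60) and the NF-kB inhibitor NFKBIE at 4.11 (SE 0.52). CCNL1, a cyclin linked to splicing, was at 4.04 (SE 0.49). All 10 were positive on 5 of 5 arrays, as the selection required. On the 1 h array these genes fell between 1.02 for FOS and 1.63 for H4C8.

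Among the 12 genes with the largest negative means, TUBA1A was at -3.14 (SE 0.31, 5 arrays, adjusted p = 0.000501). The 9 probes of TUBA1A ranged from -0.99 to -3.14. TUBA3C and TUBA4A, also alpha-tubulins, were at -2.98 (SE 0.29) and -2.73 (SE 0.30), and tubulin genes are alike enough that a clone may pick up more than its own transcript. TSPAN13, a tetraspanin of the cell membrane, was at -3.09 (SE 0.33). Secreted proteins on this side were COMP, a cartilage matrix protein, at -2.89 (SE 0.32), the metalloproteinase inhibitor TIMP3 at -2.81 (SE 0.25), the Wnt antagonist SFRP1 at -2.67 (SE 0.23) and the chemokine CXCL12 at -2.58 (SE 0.28). DIRAS3, a small GTPase of the Ras family, was at -2.76 (SE 0.29), and TMBIM6, a protein of the endoplasmic reticulum membrane that restrains cell death, at -2.72 (SE 0.23). STX4, a syntaxin of the plasma membrane, was at -2.61 (SE 0.25) and MALL, a membrane protein of the MAL family, at -2.56 (SE 0.25). All 12 were negative on 5 of 5 arrays, and for each of the 12 the 0 min value was the smallest in size.

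**Figure D2:**
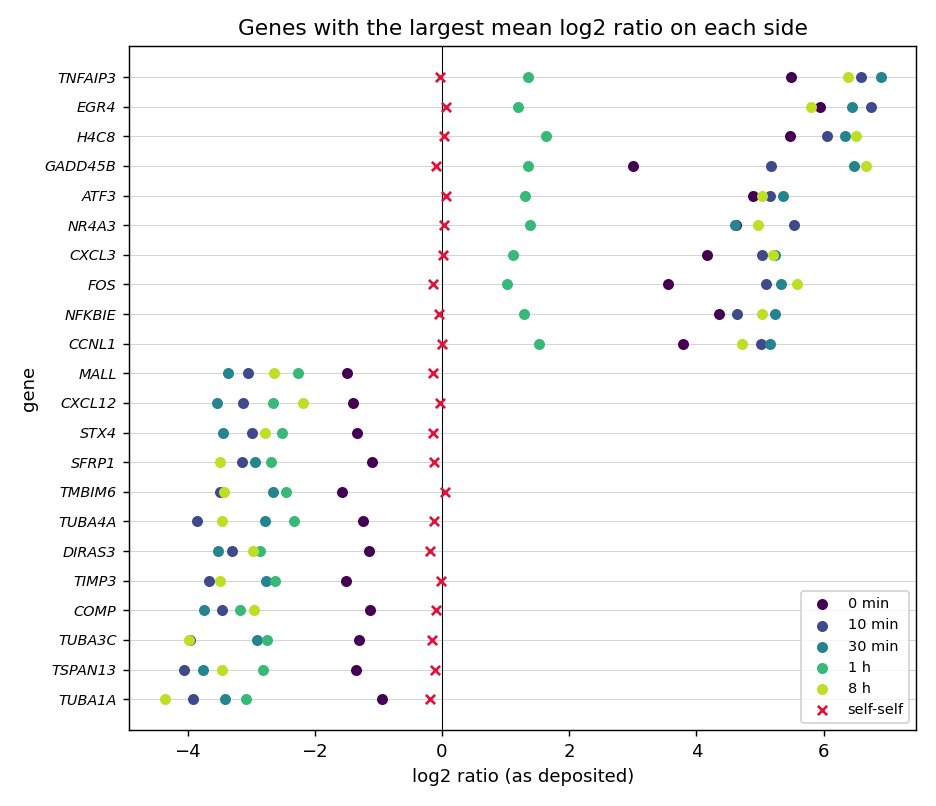
Deposited log2 ratio (horizontal axis) of 10 of the 12 genes with the largest positive and the 12 with the largest negative mean over the harvests (vertical axis), as points for each of the 5 harvests and crosses for the self-self array. TNFAIP3 ranges from 1.36 at 1 h to 6.90 at 30 min, TUBA1A from -0.94 at 0 min to -4.35 at 8 h, and the self-self crosses stay near 0.

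Of the 25 gene lists, 14 stood apart from the other genes in the mean over the harvests by camera at its preset correlation, 4 on the positive and 10 on the negative side. With an estimated correlation none did, the lowest adjusted p being 0.587. That test rests on 3 residual degrees of freedom and could hardly call any list, so its outcome alone decides nothing. The estimated correlations of the 14 lists were all above the preset 0.01. They ran from 0.05 for endoplasmic reticulum chaperones to 0.51 for immediate-early genes and 0.66 for oxidative phosphorylation. Where such correlations hold, the p-values at the preset correlation are too small, so these calls are not borne out. The same 0.587 went to interferon-stimulated genes, whose estimated correlation of -0.005 was below the preset one. List values are means over a gene's probes, and the median of all 8738 genes was 0.14, or 0.02 with each array centred on its median, so list values are to be read against it. Of these genes 3226 passed on the positive and 2208 on the negative side. Camera compares a list with the other genes and so takes this shift into account.

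The immediate-early genes and regulators with AU-rich, short-lived mRNA had the largest list median, 1.48 over 41 genes. Of these 33 passed on the positive side, 1 on the negative side and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 2.37e-06, and adjusted p = 0.587 with an estimated correlation). Beside TNFAIP3, ATF3, NR4A3 and FOS stood JUN, the partner of FOS, at 3.96 (SE 0.56), the transcription factor KLF10 at 3.89 (SE 0.52) and the NF-kB inhibitor NFKBIA at 3.77 (SE 0.53). MYC was at 2.05. The 25 cytokines and chemokines with unstable mRNA had a median of 1.10. There, 18 genes were positive and 3 negative over all genes, and 18 and 4 adjusted over the list alone (camera adjusted p = 0.0194, and adjusted p = 0.587 with an estimated correlation). IL6 was at 3.69 (SE 0.47), CXCL8 at 3.66 (SE 0.51), the adhesion molecule ICAM1 at 3.54 (SE 0.44) and the cytokine LIF at 3.31 (SE 0.50).

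Known targets of nonsense-mediated decay had a median of 0.65 over 39 genes. On the positive side 24 passed and on the negative side 3, the same counts as adjusted over the list alone (camera adjusted p = 0.00436, and adjusted p = 0.587 with an estimated correlation). Its largest members were ATF3, GADD45B at 4.29 over 2 probes, DDIT3 at 3.38 (SE 0.36) and MAP3K14, a kinase of NF-kB signalling, at 3.15 (SE 0.33). ATF3 and DDIT3 are also members of the ATF4 program, ATF3 of the immediate-early list and DDIT3 of the list of endoplasmic reticulum chaperones. SRSF3, a splicing factor, was at 1.89 (SE 0.22). Histone genes had a median of 1.30 over 23 genes, with 14 positive and 3 negative, and the same adjusted over the list alone (camera adjusted p = 0.0194, and adjusted p = 0.587 with an estimated correlation). Without the 0 min array the list's adjusted p was 0.0605, within a range from 0.00105 to 0.587 over its alternatives. H4C8 over 2 probes was at 4.51 (SE 0.53), H4C5 at 3.72 (SE 0.39), H2BC5 at 2.70 (SE 0.24) and H2AC6 at 2.66 (SE 0.29). Probes for histone genes of near-identical sequence may report the same transcripts, so the number of independent members is uncertain.

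Genes for the extracellular matrix and other fibroblast markers had the lowest list median, -0.87 over 30 genes. Of these 22 passed on the negative side and 2 on the positive side, and 23 and 2 adjusted over the list alone (camera adjusted p = 2.41e-07, and adjusted p = 0.587 with an estimated correlation). TIMP3 led the list, followed by the matrix-degrading protease MMP3 at -1.83 (SE 0.24), the collagen chain COL1A1 at -1.68 (SE 0.17) and the matrix protein SPARC at -1.53 (SE 0.18). Glycolysis genes had a median of -0.64 over 15 genes, with 12 negative and 1 positive, the same adjusted over the list alone (camera adjusted p = 0.000165, and adjusted p = 0.587 with an estimated correlation). The positive member was the glucose transporter SLC2A3 at 2.06 (SE 0.21), while PGK1 was at -1.70 (SE 0.16), LDHB at -1.44 (SE 0.17) and PFKP at -1.38 (SE 0.17). The 18 genes for chaperones of the endoplasmic reticulum and the unfolded protein response had a median of -0.62, with 11 negative and 4 positive, the same adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.587 with an estimated correlation). DDIT3 was the largest positive member. The disulfide isomerase PDIA4 was at -1.90 (SE 0.21), the co-chaperone DNAJB9 at -1.85 (SE 0.19) and SEL1L, which acts in protein export for degradation, at -1.32 (SE 0.13).

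Common reference genes had a median of -0.60 over 19 genes, with 13 negative and 1 positive, and 13 and 2 adjusted over the list alone (camera adjusted p = 0.000341, and adjusted p = 0.587 with an estimated correlation). The largest were PGK1, the transferrin receptor TFRC at -1.34 (SE 0.15), ENO1 at -1.32 (SE 0.17) and HPRT1 at -1.06 (SE 0.13). Genes of this kind set the zero of each slide, per the labels, although which ones were used is not stated there. Of the 67 nuclear genes of oxidative phosphorylation, 48 were negative and 2 positive, with 51 and 2 adjusted over the list alone. Their median was -0.56 (camera adjusted p = 4.54e-10, and adjusted p = 0.587 with an estimated correlation). ATP5MC1 was at -1.23 (SE 0.17), ATP5F1B at -1.20 (SE 0.15) and ATP5MC3 at -1.18 (SE 0.15), all parts of ATP synthase, and SDHC of complex II at 1.00 (SE 0.19). Ribosomal protein genes had a median of -0.55 over 53 genes, with 34 negative and 7 positive, and 35 and 7 adjusted over the list alone (camera adjusted p = 5.89e-06, and adjusted p = 0.587 with an estimated correlation). The members farthest from 0 lay on both sides, RPS12 at 1.66 (SE 0.23), FAU at -1.38 (SE 0.16), RPL28 at 1.38 (SE 0.17) and RPL17 at 0.96 (SE 0.17). On the self-self array the medians of oxidative phosphorylation and ribosomal protein genes were -0.17 and -0.15, also negative.

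Genes for the G1/S transition and DNA replication had a median of -0.42 over 32 genes, with 17 negative and 2 positive, the same adjusted over the list alone (camera adjusted p = 0.000482, and adjusted p = 0.587 with an estimated correlation). The ribonucleotide reductase subunit RRM2 was at -1.73 (SE 0.26), cyclin D1 (CCND1) at -1.57 (SE 0.14), GINS2 at -1.51 (SE 0.23) and PCNA at -1.21 (SE 0.19). Cytosolic chaperones had a median of -0.39 over 22 genes, with 11 negative and 5 positive, the same adjusted over the list alone (camera adjusted p = 0.0257, and adjusted p = 0.587 with an estimated correlation). HSPA8 was at -2.43 (SE 0.22), HSPD1 at -1.54 (SE 0.14), CCT3 at -1.42 (SE 0.16) and DNAJB1 at 1.06 (SE 0.14). Proteasome genes had a median of -0.33 over 34 genes, with 19 negative and 7 positive, and 20 and 7 adjusted over the list alone (camera adjusted p = 0.00792, and adjusted p = 0.666 with an estimated correlation). PSMD2 was at -1.08 (SE 0.14), PSMD10 at -1.05 (SE 0.14), PSMB6 at -1.04 (SE 0.15) and PSMA7 at -0.97 (SE 0.14). Translation factors had a median of -0.26 over 28 genes, with 13 negative and 4 positive, the same adjusted over the list alone (camera adjusted p = 0.00942, and adjusted p = 0.587 with an estimated correlation). EIF5 was at -1.65 (SE 0.19) and EIF4A2 at 1.05 (SE 0.15), with EIF1AX at -0.93 (SE 0.16) and EIF3I at -0.90 (SE 0.14). With fry, which asks whether a list's genes move 1 way without comparing them with other genes, the adjusted p-values of ribosomal proteins, translation factors, proteasome and oxidative phosphorylation were 0.0582, 0.0501, 0.0988 and 0.0501.

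**Figure D3:**
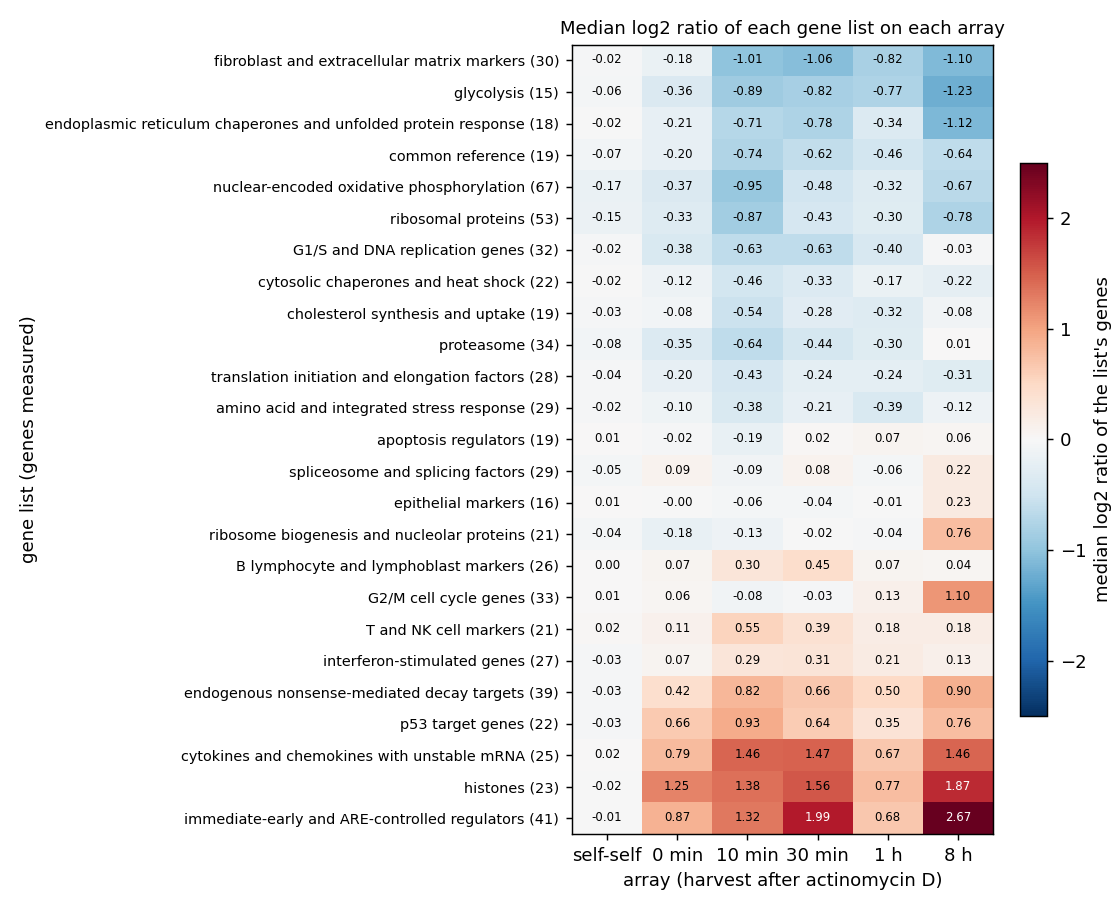
Median deposited log2 ratio (colour and number) of each of the 25 gene lists (vertical axis, genes measured in parentheses) on each of the 6 arrays (horizontal axis). The immediate-early list runs from 0.87 at 0 min to 2.67 at 8 h with 0.68 at 1 h. The extracellular matrix list goes from -0.18 at 0 min to -1.01 at 10 min and stands at -1.10 at 8 h. The G2/M list reaches 1.10 at 8 h only.

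The other 11 lists did not pass in the mean, although many of their genes did. The 22 p53 target genes had a median of 0.74, with 14 positive and 3 negative over all genes and over the list alone (camera adjusted p = 0.0685). The list passed in 6 of 10 alternatives, among them without the 30 min, 1 h or 8 h array (adjusted p = 0.0425, 0.0122 and 0.0449), and had an adjusted p of 0.62 with an estimated correlation. The kinase PLK2 was at 3.21 (SE 0.36), the cell death gene BBC3 at 2.29 (SE 0.31), the death receptor TNFRSF10B at 1.92 (SE 0.22) and the nuclease AEN at 1.70 (SE 0.21). Of 29 genes of the ATF4 program, 8 were positive and 13 negative, the same adjusted over the list alone, with a median of -0.17 but a mean of 0.03 (camera adjusted p = 0.13, on the negative side). The transcription factors ATF3, DDIT3 and CEBPB stood at 4.35, 3.38 and 1.76, while the amino acid transporters SLC7A5 and SLC1A5 were at -1.64 and -1.53. Without the 0 min array the list's adjusted p was 0.0492, within a range from 0.0492 to 0.734 over its alternatives. Of 33 G2/M genes, 14 were positive and 5 negative, the same adjusted over the list alone (median 0.24, camera adjusted p = 0.419). CKS2 was at 1.21, BIRC5 at -1.02, CDC25C at 0.95 and STMN1 at -0.92. Of 27 interferon-stimulated genes, 13 were positive and 4 negative, the same adjusted over the list alone (median 0.30, camera adjusted p = 0.41, and fry adjusted p = 0.0358). IFIT2 was at 1.35, OAS1 at -1.06, OASL at 0.94 and IRF9 at 0.83.

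Cholesterol genes split 6 positive to 10 negative of 19, and 6 to 11 adjusted over the list alone (median -0.34, camera adjusted p = 0.248), with LSS at 1.15, DHCR7 at 1.09, SCD at -1.08 and FASN at 0.98. Spliceosome genes split 10 to 9 of 29, the same adjusted over the list alone (median 0.04 as deposited, -0.08 with arrays centred and -0.04 without the 30 min array, mean 0.08, camera adjusted p = 0.716, on the negative side), with HNRNPA1 at -1.25, HNRNPC at 1.11, HNRNPF at 1.11 and SF3B1 at 0.93. Apoptosis regulators split 8 to 6 of 19, the same adjusted over the list alone (median -0.03 and mean 0.24, camera adjusted p = 0.691, on the negative side), with MCL1 at 2.97, PMAIP1 at 1.24 and BIRC2 at 1.12. Genes of ribosome biogenesis split 6 to 6 of 21, the same adjusted over the list alone (median 0.18 but -0.02 without the 8 h array, mean 0.05, camera adjusted p = 0.805, on the negative side), with NHP2 at -1.30, DDX10 at 1.24, FBL at -1.08 and NOP2 at 0.86. The marker lists of B lymphocytes, T and NK cells and epithelium did not pass in the mean. B lymphocyte markers had 8 positive and 0 negative of 26, and 4 and 0 adjusted over the list alone (median 0.18, camera adjusted p = 0.356), led by the kinase BLK at 2.53. T and NK cell markers had 10 and 0 of 21, and 6 and 0 adjusted over the list alone (median 0.29, camera adjusted p = 0.192), led by IL7R at 1.77. Epithelial markers had 3 and 2 of 16, and 2 and 2 adjusted over the list alone (median 0.11 as deposited and -0.0064 with arrays centred, mean -0.03, camera adjusted p = 0.75, on the negative side), with KRT18 at -1.22.

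The slope of the log ratio over time asks whether the ratio between treated and untreated cells changes once transcription has stopped. Its sign gives the direction of that change, not whether the ratio moves away from 0 or towards it. No probe passed, although SNAI2, a repressor of epithelial genes known as Slug, came closest. Its log ratio ran from -0.64 at 0 min through 0.91 at 30 min to 4.61 at 8 h, a slope of 0.97 (SE 0.09) per unit of log2(1 + min / 10). With limma 0 of 13140 probes had an adjusted p under 0.05, the lowest being 0.0672 for SNAI2, and 1869 (14.2%) had an unadjusted p under 0.05. The count depends on the setting. It was 21 with robust moderation, 18 positive and 3 negative, and 437 with linear minutes, 425 positive and 12 negative. Without the 1 h array it was 584, 523 positive and 61 negative, and without any other array 0, with 389 probes at an unadjusted p under 0.05 without the 8 h array. With a gene's probes averaged, SNAI2 alone passed among 8738 genes (adjusted p = 0.0427), where 1305 genes had an unadjusted p under 0.05, and centring each array also left SNAI2 alone past the threshold (adjusted p = 0.0495).

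The other genes with the smallest p-values on the positive side, none past the threshold, were DKK1, a secreted Wnt inhibitor, with a slope of 0.74 (SE 0.09) and 2.95 at 8 h, and KLHL21, an adaptor of a ubiquitin ligase, with 0.54 (SE 0.07). ARRDC3, an arrestin-like protein, had 0.54 (SE 0.07), MACIR 0.54 (SE 0.07) and HJURP, a chaperone of the centromeric histone CENP-A, 0.48 (SE 0.06). The value of MACIR is of 1 probe, and with its probes averaged the slope was 0.385 (SE 0.06). On the negative side TLN1, which links integrins to actin, had -0.64 (SE 0.09) and went from 2.21 at 0 min to -1.17 at 8 h. These values are of 1 probe. With the probes of TLN1 averaged the slope was -0.48 (SE 0.07), from 1.41 at 0 min to -1.14 at 8 h. FOXA1, a transcription factor that opens chromatin, had -0.45 (SE 0.06), LIMK1, a kinase that acts on cofilin, -0.44 (SE 0.08), the zinc finger gene ZNF574 -0.42 (SE 0.06), the Golgi membrane protein GOLIM4 -0.41 (SE 0.07) and IGFBP5, which binds insulin-like growth factors, -0.38 (SE 0.06). Unless called averaged, the slopes of these 11 genes are of 1 probe each, and for IGFBP5 no slope with probes averaged is given here. The adjusted p-values of these 11 genes lay between 0.0823 and 0.0998.

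**Figure D4:**
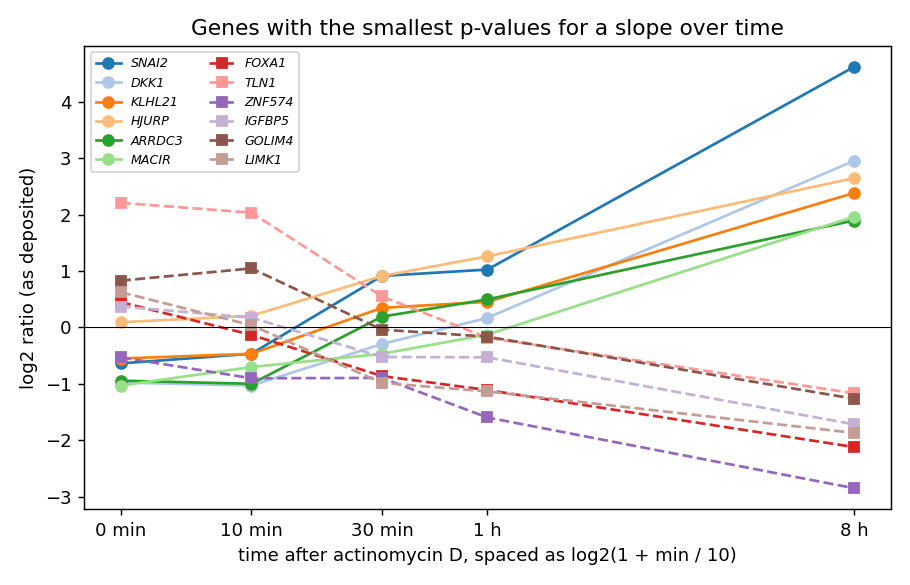
Deposited log2 ratio (vertical axis) over time after actinomycin D (horizontal axis, spaced as log2(1 + min / 10)) for the 12 genes with the smallest slope p-values, 6 on each side, none past an adjusted p of 0.05. SNAI2 reaches 4.61 at 8 h and ZNF574 -2.85.

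Of the 25 lists, 10 passed for the slope by camera at its preset correlation, and 0 with an estimated correlation (lowest adjusted p 0.911) or with fry (lowest adjusted p 0.213, for ribosome biogenesis). As for the mean, the test with an estimated correlation rests on 3 residual degrees of freedom and could hardly call any list. The estimated correlations of these 10 lists ran from 0.04 for cholesterol genes to 0.58 for glycolysis, all above the preset 0.01. Their p-values at the preset correlation may therefore be too small. No member of any list passed over all genes. G2/M genes had the largest median slope, 0.18 over 33 genes, with 9 positive adjusted over the list alone (camera adjusted p = 1.5e-07, and adjusted p = 0.911 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, went from -0.35 at 0 min to 1.95 at 8 h, and the mitotic kinase PLK1 from -0.26 to 1.29. The list's median was 0.06 at 0 min and 1.10 at 8 h, and without the 8 h array its slope was -0.01 (adjusted p = 0.907). Ribosome biogenesis genes had a median slope of 0.14 over 21 genes, with 8 positive adjusted over the list alone (camera adjusted p = 0.000216, and adjusted p = 0.911 with an estimated correlation). NOB1, which acts late in making the small ribosomal subunit, went from -0.05 at 0 min to 2.06 at 8 h, and BYSL from -0.20 to 2.12. Proteasome genes had a median slope of 0.075 over 34 genes, with 0 past the threshold adjusted over the list alone (camera adjusted p = 0.00812, and adjusted p = 0.991 with an estimated correlation). Their adjusted p was 0.0881 without the 10 min array and 0.278 without the 8 h array, within a range from 2.17e-05 to 0.991 over the alternatives. Leaving out an array was chosen for list slopes after seeing the data.

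Extracellular matrix genes had the lowest median slope, -0.12 over 30 genes, with 3 negative adjusted over the list alone (camera adjusted p = 1.5e-07, and adjusted p = 0.911 with an estimated correlation). COL1A1 went from 0.01 at 0 min to -3.02 at 8 h and COL4A1 from 1.62 to -1.95. The list's median was -0.18 at 0 min, -1.01 at 10 min, -1.06 at 30 min, -0.82 at 1 h and -1.10 at 8 h. Nearly all of the change in this median thus lay between the 0 and 10 min arrays. With arrays scaled to equal spread, an alternative chosen after seeing the data, this list had an adjusted p of 0.155, within a range from 1.97e-10 to 0.911 over its alternatives. The list of endoplasmic reticulum chaperones had -0.090 over 18 genes, with 1 negative adjusted over the list alone (camera adjusted p = 0.00417, and adjusted p = 0.911 with an estimated correlation). Glycolysis genes had -0.093, reference genes -0.075 and ribosomal protein genes -0.048, where scaling turned glycolysis and ribosomal protein genes to the positive side and left reference genes at a median of 0.000746 with the test still negative, with none past the threshold adjusted over each list alone (camera adjusted p = 0.0301, 0.00812 and 0.0222, and adjusted p = 0.991 with an estimated correlation for each). Cholesterol genes and T and NK cell markers both had -0.020, with none adjusted over each list alone (camera adjusted p = 0.0371 for both, and adjusted p = 0.911 and 0.991 with an estimated correlation). Without the 0 min array 6 lists passed, and the adjusted p-values of chaperones of the endoplasmic reticulum, glycolysis, reference, ribosomal protein and cholesterol genes were 0.0719, 0.816, 0.592, 0.486 and 0.364. With scaling to equal spread they were 0.346, 0.843, 0.843, 0.416 and 0.193. Without the 8 h array the endoplasmic reticulum list had an adjusted p of 0.278, and the slopes of ribosomal protein genes (adjusted p = 0.353) and of T and NK cell markers (adjusted p = 0.907) lay on the positive side. The T and NK cell markers had an adjusted p of 0.297 without the 10 min array. Over their alternatives the adjusted p-values of these lists reached from 2.71e-05 to 0.991.

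The remaining 15 lists did not pass for the slope, with adjusted p-values from 0.203 for G1/S genes to 0.978. Median and test differed in sign for the ATF4 program, cytokines and cytosolic chaperones, whose medians were positive, and the mean was positive and the test negative for histones and B lymphocyte markers. Adjusted over the list alone, 7 immediate-early genes, 3 spliceosome genes, 2 chaperone genes, 1 B lymphocyte marker and 1 epithelial marker had a positive slope. The immediate-early list had a median slope of 0.02 (camera adjusted p = 0.415), and its adjusted p was 0.00429 on the positive side without the 1 h array and 0.0133 on the negative side without the 8 h array, within a range from 0.00149 to 0.991 over its alternatives. Scaling turned this list's slope to -0.11 (adjusted p = 0.00149). Without the 8 h array the ATF4 program, cytokines, histones and p53 targets passed on the negative side (adjusted p = 0.0133, 0.0254, 0.0104 and 0.0326) and oxidative phosphorylation on the positive side (adjusted p = 0.0107). Oxidative phosphorylation passed on the negative side without the 10 min array (adjusted p = 0.00113), and G1/S genes on the positive side without the 0 min array (adjusted p = 0.00277). With scaling to equal spread, nonsense-mediated decay targets, cytokines and histones passed on the negative side (adjusted p = 0.0309, 0.00172 and 0.000226), and G1/S genes and oxidative phosphorylation on the positive side (adjusted p = 0.00149 and 0.000297). Over the alternatives of these lists adjusted p-values ran from 0.000226 to 0.998.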

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

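The 3 tests of the 1 h array and the count of harvest orders at an unadjusted p were chosen only after the results were seen. Among 24 genes chosen for their mean, 9 had a harvest that stood far from the other 4, by a gap of more than 0.71 of the range. Chance gives about 1 in 20 such cases where arrays are replicates, and these 5 arrays differ in time. Of the 9, 8 were at 1 h: TNFAIP3 at 1.36, EGR4 at 1.19, H4C8 at 1.63, ATF3 at 1.31, NR4A3 at 1.38, CXCL3 at 1.12, NFKBIE at 1.29 and a gene not described here at 1.23, against values from 4.17 to 6.90 at the other harvests. The remaining one was DIRAS3 at 0 min, at -1.15 against -3.52 to -2.87.

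On the 1 h array positive log ratios were small while negative ones were not. Against the mean of 30 min and 8 h, the 1 h value rose with a slope of 0.28 (SE 0.01) over 1871 probes above 1 and of 0.79 (SE 0.02) over 1125 probes below -1, a ratio of 2.81, which argues against a common scale factor on all log ratios of that array. Signal added to the denominator channel, from background or spectral bleed, could level off large positive ratios, and the median at 1 h was 0.25 higher in probes above 4 than in those from 2 to 3. A change of the RNA itself at 1 h could do so too, with 0 of 163 probes above 3 that were not lower at 1 h than at both other times. These last 2 cannot be told apart, since 1 array was made at 1 h and ratios hold no brightness.

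Slopes over time that differed from those of other genes were found for 10 lists: G2/M genes at 0.18, ribosome biogenesis at 0.14, proteasome at 0.075, extracellular matrix at -0.12, endoplasmic reticulum chaperones at -0.090, glycolysis at -0.093, reference genes at -0.075, ribosomal proteins at -0.048, cholesterol genes at -0.020 and T and NK cell markers at -0.020. Scaling to equal spread turned glycolysis and ribosomal protein genes to the positive side. Without the 8 h array the slope of G2/M genes was -0.015 (adjusted p = 0.907), and ribosomal protein genes and T and NK cell markers lay on the positive side (adjusted p = 0.353 and 0.907). None of the 10 passed with an estimated correlation or with fry. The 8 h array was left out after the results were seen. Besides these, SNAI2 had a slope of 0.97 with probes averaged.

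The real order of the harvests gave 0 probes with a slope past the adjusted threshold, so all 100 orders drawn, the real one included, reach that count whatever the data, and it decides nothing. The highest other count was 182. At an unadjusted p under 0.05, 7 of 100 orders gave at least as many as the real order's 1869, the highest other count being 2258, so chance in the order was not excluded for that count.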

How the results depend on the processing

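Scaling of arrays for list means and slopes, leaving out each harvest for list slopes and for probes beyond the range on the same side at every harvest, and keeping the repeated value were added after seeing the data. The mean over the harvests passed for a similar number of probes in 12 of 13 alternatives, with 6224 to 7962 when a harvest was left out and 8244 with the repeated value kept. Against the self-self array 2 passed, which follows from resting the comparison on 1 array. The 24 genes chosen for the mean, run in 8 of the alternatives, passed on the same side with centring, scaling and each harvest left out, and did not pass against the self-self array. They were chosen on the same arrays, so these runs are no independent check of them. Of the 25 lists, 14 to 15 passed in the mean when a harvest was left out, and 0 with an estimated correlation. The cause was not tested.

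The counts beyond the self-self range became 8, 0, 0, 18 and 0 at 0, 10 and 30 min, 1 h and 8 h with arrays scaled to equal spread, which by construction removes the difference in spread they measure. With a limit of 1 log2 unit they became 952, 3623, 2746, 1087 and 3670, a wider range than the self-self array's. The remaining alternatives stayed within 1.5 times. The mean r of the self-self array with the harvests moved to 0.35 as Spearman's rank correlation, and the cause was not tested.

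The count of probes with a slope was 1 with centring, 437 with linear minutes, 21 with robust moderation and 1 with probes averaged, and ranged from 0 to 584 when a harvest was left out, the highest without 1 h. The cause was not tested. Lists with a slope numbered 0 with an estimated correlation and 6 to 11 when a harvest was left out. Slopes turned with scaling for ribosomal proteins (0.027, adjusted p = 0.416) and glycolysis (0.0044, adjusted p = 0.843). Without 8 h they turned for ribosomal proteins, G2/M genes and T and NK cell markers, whose slopes ran from -0.086 to 0.064, from -0.015 to 0.24 and from -0.083 to 0.021 when a harvest was left out. The cause was not tested. Ribosome biogenesis kept its slope call in 9 of 10 alternatives and lost it with an estimated correlation (adjusted p = 0.911), and fry, run beside these, did not call it (adjusted p = 0.213). No paired analysis was possible because each time has 1 array and the labels give no replicate numbers shared between groups. Signal over background is not given by ratios, so dim probes were not filtered here.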

Other observations

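The tests of tubulin genes, of the early secretory pathway, and of dye bias by size of the mean were chosen only after the results were seen. Most tubulin genes lay on the negative side beyond the named TUBA1A, TUBA3C and TUBA4A. Of 11 measured, 9 passed on the negative and 1 on the positive side, and without the 3 named ones the median of the other 8 was -1.02, below 9999 of 10000 random lists of that size. TUBG1 was at -1.59 (SE 0.20), TUBB4B at -1.43 (SE 0.18) and TUBB6 at -1.12 (SE 0.14), while TUBB2B was at 0.61 (SE 0.16). The alpha-tubulin TUBA1B was at 0.23 (SE 0.10) and did not pass. Tubulin clones may pick up more than their own transcripts, so the number of independent members is uncertain. Genes for entry into the endoplasmic reticulum and early secretory transport behaved alike. Of 51 measured, 40 passed on the negative side and 3 on the positive side, and without the 6 that prompted the list the median of 45 was -0.79, below all 10000 random lists. RPN1, a subunit of the enzyme that attaches sugar chains, was at -1.77 (SE 0.19), the retrieval receptor KDELR1 at -1.63 (SE 0.16) and the translocon-associated SSR1 at -1.58 (SE 0.19). With arrays centred or scaled the medians stayed negative, at -1.14 and -1.01 for tubulins and -0.91 and -0.83 for the secretory list. Both sets may shift as families, a hypothesis from the same data, tested against random lists that ignore correlation between genes.

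Zinc finger genes of the ZNF family lay on the other side. Over 121 genes the median was 0.41, above all 10000 random lists, with 72 genes positive and 12 negative. ZNF217 was at 2.34 (SE 0.28), ZNF317 at 2.12 (SE 0.26) and ZNF24 at 2.02 (SE 0.25), and ZNF574 at -1.35. Centred or scaled, the median was 0.29 or 0.41, where that of all genes was 0.02 or 0.12. Many ZNF genes share sequence, so their probes may not be independent, which neither this median nor the random lists settle.

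The sign of the ratio was tested through the preset list of immediate-early genes and regulators with AU-rich mRNA, whose transcripts are known to accumulate when translation is blocked. Its median of 1.48 lay above all 10000 random lists of 41 genes, the highest of which reached 0.61. Random lists ignore correlation between genes, estimated at 0.51 for this list, and with it the list did not pass (camera adjusted p = 0.587). That test rests on 3 residual degrees of freedom and could hardly pass, so it does not decide. If the estimate of 0.51 holds, the random lists overstate how far this list stands apart. The side of the median is consistent with emetine-treated RNA in the numerator. It remains a hypothesis, since that list's direction was taken from general knowledge and no label states the numerator.

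A dye bias of single probes would be shared by all arrays, because treated RNA carried the same dye throughout. Among 1985 probes that passed with a mean of at least 1 in size, the self-self value turned to the side of the mean had a median of 0.056, against a median size of 1.32. Among 2166 that passed with a mean under 0.5 it was 0.042, against 0.41. The self-self value lay on the side of the mean for 69.0% of the first set and 66.0% of the second, which leaves room for a small shared bias in both. The size of the medians argues against dye bias as the main source of either set. Across all probes the self-self value and the mean over the harvests correlated at r = 0.257, below the 0.3 set beforehand as its limit but by less than the spread between arrays, so a smaller part could come from dye bias.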
